A study of Mus musculus with 15 samples.

How the data were processed

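RNA-seq was done on mouse embryonic stem cells of 5 lines in 2i medium, with 3 replicates per line that the series' design text calls biological. Per the labels' protocols, total RNA was cleared of small RNA, depleted of ribosomal RNA and fragmented before library preparation. Reads were aligned with TopHat, counted with featureCounts and compared with DESeq2, per the submitters' processing notes, on GRCm38 (mm10). Versions, settings, filters and the use of strand in counting are not given in the sources used here. Gene identifiers are those of Ensembl release 72, per the file headers.

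The authors deposited 1 table of 38355 genes with log2 fold changes and a true or false call for each of 4 comparisons. The log2 fold changes are those the authors obtained from DESeq2, per the file headers. The criteria of the call are not given in the sources used here. Each called gene has an absolute log2 fold change above 1, the smallest being 1.06, 1.01, 1.00 and 1.01 for Ezh2-KO, Suz12-KO, Ring1A+B-DKO and the wild-type lines. The planned test with replicates could not be used on such values, counts adjusted over the list alone could not be had without p, and the authors' call stands where an adjusted p had been foreseen. No SD, standard error or p per gene is given, and depth per sample is unknown. Replicates could not be compared with each other.

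The direction of each column was tested on the table itself. A missing value was read as no read in either group, and 13 of the 16 patterns of missing values can occur under that reading. Those 13 were seen, and the other 3 held no gene. Genes with reads in the named group but none in its control must then be positive if the column is named group over control. In Ezh2-KO 922 of 922 such genes were positive. In Suz12-KO 1064 of 1064, in Ring1A+B-DKO 2259 of 2259 and between the wild-type lines 1170 of 1170 were negative. Those 3 columns therefore hold E14-WT over the named group, opposite to the order in their headers, and their signs were turned. The same rule recovered the sign of 80 of 80 columns in data simulated for 5 groups with 5000 genes. Those data were built with the same reading of missing values, so this checks the working of the rule and not that reading.

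The fold changes appear to be drawn towards 0 for genes with few reads. The 922 genes with no reads in Ezh2-WT had a median absolute log2 fold change of 0.085 in Ezh2-KO, and the 2259 with none in E14-WT one of 0.20 in Ring1A+B-DKO. Between 30.6% and 31.4% of values in each comparison are shared by several genes. Sizes therefore understate changes of weakly expressed genes and are not on one scale across comparisons.

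Symbols and coordinates came from GENCODE mouse release 21 on the same assembly, which matched 36602 of 38355 identifiers (95.4%). Of 544 genes printed or held in the lists, 246 overlap another annotated gene and 185 an antisense one, so their reads could be divided or, without strand, mixed. Near-identical copies were sought with blastn 2.17.0 at 95% identity over at least 100 nt and 50% of the shorter transcript.

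The 23 gene lists and the rule for named genes were fixed before the data were examined. The rule named the deleted genes, then in each knockout comparison the 10 largest increases and 10 largest decreases called, with a symbol that is not a Gm or Rik model. It added up to 4 members per list with the largest change in either PRC2 knockout, and the 10 increases and 5 decreases with the largest smaller value in both. The same limits of 10 were later applied to the comparison of the wild-type lines. Other genes are called members of lists, members of overlaps, copies of named genes or genes near Ring1, and were chosen after their values were seen. Each list's median was placed among the medians of 10000 random lists of the same size, outside meaning beyond their central 99%. Over 92 lists and comparisons 0.92 would lie outside by chance if genes were independent. For simulated lists of 25 genes in Ring1A+B-DKO, drawn from 19693 genes, 0%, 96.0% and 100% of 200 lay outside with a planted shift of 0, 0.5 and 1. Fisher's exact tests across genes were one-sided for lists and overlaps, and genes are not independent replicates. The chance correlation from a shared group was simulated for 16000 genes with 3 libraries per group and equal spread.

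Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Alternatives were other size thresholds, centring, the mean of lists, Spearman's rho and a trimmed correlation. Those added later were counts by size alone, the sign in the headers, genes with a value of their own, random lists matched on shared values and lists of genes with reads in the control. Leaving out replicates, a replicate block and other count models need values per sample and were not run.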

Results

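RNA was sequenced from mouse embryonic stem cells kept in 2i medium, in which inhibitors of MEK and GSK3, with LIF, hold the cells in the naive pluripotent state. There were 15 samples in 5 groups of 3 replicates. E14-WT is the wild-type line E14TG2a, and Ezh2-WT is a second wild-type line with both Ezh2 alleles floxed. Ezh2-KO and Suz12-KO each lack a core subunit of Polycomb repressive complex 2 (PRC2), which methylates lysine 27 of histone H3. Ring1A+B-DKO lacks Ring1A (gene Ring1) and Ring1B (gene Rnf2), the ubiquitin ligases of Polycomb repressive complex 1 (PRC1). All fold changes and calls below are those of the authors' deposited table, which covers 38355 genes and 4 comparisons. It gives a log2 fold change and a yes or no call per gene and comparison, without p-values, standard errors or values per sample. Errors for single genes and the depth of each sample are therefore unknown here. Fold changes are given as the named group over its control. For the 3 comparisons against E14-WT this is the opposite of the sign in the deposited columns, for reasons given with the processing. A gene is said to rise or fall only where the authors called it. Differences between comparisons could not be tested without errors. No wild type of the Ring1A+B-DKO line is among the groups, and the parental line of Suz12-KO is not stated, so their comparisons also hold any difference between lines.

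The authors called 32 genes in Ezh2-KO, 37 in Suz12-KO, 591 in Ring1A+B-DKO and 113 between the wild-type lines. These are 0.177%, 0.200%, 3.00% and 0.607% of the 18097, 18498, 19693 and 18604 genes with a value in the authors' deposited table. Protein-coding genes made up 28, 31, 544 and 98 of the calls.

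**Figure D1:**
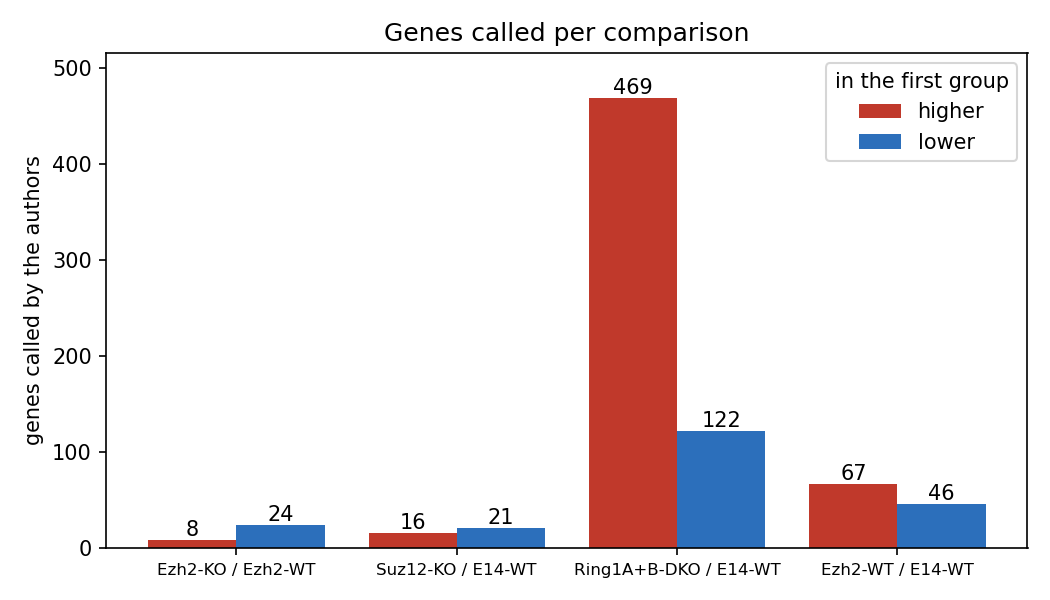
Genes called by the authors in each comparison (vertical axis, number of genes), split into those higher (red) and lower (blue) in the group named first. Ring1A+B-DKO had 469 genes higher and 122 lower, against 8 and 24 in Ezh2-KO and 16 and 21 in Suz12-KO.

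The deleted genes were read first. In the authors' deposited table, Ring1 (ENSMUSG00000024325, chromosome 17, 34020792 to 34024680 in GRCm38) fell in Ring1A+B-DKO, with a log2 fold change of -2.03. Rnf2 (ENSMUSG00000026484, chromosome 1, 151458004 to 151500955) stood at 0.17 in the same cells and was not called. Suz12 (ENSMUSG00000017548, chromosome 11, 79993106 to 80034123) stood at -1.04 in Suz12-KO, also without a call. Ezh2 (ENSMUSG00000029687, chromosome 6, 47530139 to 47595341) stood at -0.14 in Ezh2-KO. The labels do not say which exons were removed, and one value per gene also covers the exons that remain, so the values of Ezh2, Rnf2 and Suz12 check the labels little. Ezh2, Suz12 and Rnf2 also overlap other annotated genes.

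The comparison of Ezh2-KO with Ezh2-WT asks which transcripts depend on Ezh2, a methyltransferase of PRC2, in 2i. According to the authors' deposited table, 8 genes rose and 24 fell. The largest decrease was that of Gata2 (ENSMUSG00000015053, chromosome 6, 88193891 to 88207032), a haematopoietic transcription factor, at a log2 fold change of -2.68. Tgfbi, a secreted matrix protein, and Sdc3, a heparan sulphate proteoglycan, both fell, to -2.10. App, the amyloid precursor protein, fell by 1.90 on the log2 scale, and the Notch ligand Dll1 by 1.80. Fmnl1, Rab3il1, Bhlhe41, Ripply3 and Adcy1 completed the 10 largest decreases, at -1.86, -1.72, -1.58, -1.58 and -1.57. Among the 8 increases were the calcium-binding protein gene S100a6 at 1.86, Dpysl5 at 1.53, the cyclin D1 gene Ccnd1 at 1.31, Gsto1 at 1.19 and the kinase gene Sgk1 at 1.06. The other 3 were the small RNA genes Mir5099, Rny1 and Mir292, at 1.57, 1.47 and 1.30. Small RNA was removed before the libraries were made, so these 3 values are uncertain. Gata2, Sdc3, Bhlhe41, Ripply3, S100a6, Ccnd1, Sgk1 and Mir5099 were also called between the wild-type lines, in the opposite direction.

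Hox genes and developmental transcription factors, classes that Polycomb complexes are known to occupy in stem cells, had 0 called increases in Ezh2-KO in the authors' deposited table. Of 18 Hox genes with a value, 0 were called, and their median log2 fold change was -0.09. Of 52 developmental transcription factors, 0 rose and 1, Gata2, fell, with a median of -0.07. Both medians lay within the central 99% of random lists of the same size. With so few calls, only 0.0080 and 0.023 increases were expected for lists of these sizes, so 0 increases says little about these classes. Uncalled members reached 1.21 for Ebf1 and 1.17 for Olig2. The germline and meiosis list had 0 calls among 22 members, against 0.0097 increases expected. Of the 23 lists, 2 lay outside that range, both below it and with 0 calls each. They were endoderm (median -0.18 over 21 genes) and p53 targets (-0.20 over 18 genes), the latter within the range once random lists were matched on shared values (percentile 0.84). Imprinted genes had 1 call among 28, Grb10 at -1.22, and WNT targets 1 among 12, Ccnd1. The table also holds 122 genes with an absolute log2 fold change of at least 1, of which 90 were not called, and 3 called genes with one of at least 2.

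The comparison of Suz12-KO with E14-WT asks the same of a second PRC2 subunit. The authors' deposited table had 16 genes that rose and 21 that fell. The testis histone H1 gene Hist1h1t rose most, at a log2 fold change of 1.91. The X-linked homeobox gene Rhox5 (ENSMUSG00000095180, chromosome X, 37804842 to 37808876) rose by 1.72, the kinase gene Lck by 1.65 and the germ cell and naive marker Dppa3 by 1.54. Mir5099, B3gnt3, Sfmbt2, the vimentin gene Vim, the Nodal antagonist Lefty2 and Klhl13 followed at 1.59, 1.51, 1.44, 1.44, 1.31 and 1.29. The largest decreases were in the gene models 2210409E12Rik (-2.56), G430049J08Rik (-2.42) and Gm16344 (-2.14). Other decreases were those of BC067074 at -1.89, Gpa33 at -1.85, the aggrecan gene Acan at -1.81 and the laminin gene Lamb1 at -1.80. Dusp27, Trpm1, the endocytic receptor gene Lrp2, Phf11d, Klhdc7a and Grb10 fell to -1.71, -1.69, -1.66, -1.55, -1.54 and -1.48. Lefty2 shares a near-identical stretch with Lefty1, and Dppa3, Klhdc7a, Phf11d and the gene models 2210409E12Rik, G430049J08Rik and Gm16344 have near-identical copies as well, so their values are uncertain. Ccnd1, at 1.07, and Mir5099 and Vim were higher here and lower in Ezh2-WT than in E14-WT.

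Hox genes and developmental transcription factors had 0 calls in Suz12-KO, over 15 and 58 members with a value in the authors' deposited table, with medians of -0.11 and -0.06. Only 0.013 and 0.050 increases were expected for lists of these sizes, so 0 calls says little about them. The germline and meiosis list had 1 increase among 24 members, Rhox5, and a median of -0.19, below the central 99% of random lists. Its mean of -0.17 was within that range, at the percentile 1.09. The 2-cell-like list, genes of the early embryo seen in rare stem cells, stood at -0.65 over 10 members, all below 0 and with 0 calls. Tcstv1 and Zscan4f, for example, stood at -1.20 and -0.95. Replication-dependent histones (median 0.23, 21 genes) and ribosomal proteins (0.18, 32 genes) lay above the range, with 0 calls in either list. Ezh2-WT, with no knockout, stood on the same side of E14-WT in these 3 lists, at -0.72, 0.33 and 0.15. Tcstv1 and Zscan4f stood there at -1.30 and -1.03. In Ezh2-KO, which uses no E14-WT library, histones stood at 0.14, within the range (percentile 99.46), and ribosomal proteins at -0.04. These histones lay above the range with the mean (0.19, percentile 99.93) and with genes that had reads in Ezh2-WT (99.51). Against matched random lists they lay within it (97.2). The 2-cell-like list had only 2 values in Ezh2-KO. Neural genes had 0 calls among 15 and a median of 0.17, within the range (percentile 99.1). They were above it with the mean (0.18), matched random lists or genes with reads in E14-WT. Tubb3 stood at 0.99 and Nefl at 0.61. Endoderm had 1 decrease among 19, Lamb1, with a median of -0.10 within the range and a mean of -0.26 below it. Imprinted genes had 1 increase, Sfmbt2, and 1 decrease, Grb10, among 29. Here 152 genes had an absolute log2 fold change of at least 1, of which 115 were not called, and 3 called genes had one of at least 2.

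The 2 PRC2 knockouts share no library, and their fold changes moved partly together. Across 16426 genes with both values in the authors' deposited table, Pearson's r was 0.34 and Spearman's rho 0.29. Genes are not independent replicates, so no p is given for these, the first of 6 such correlations. Without the 5% largest absolute fold changes of either comparison r was 0.23. Ccnd1 (chromosome 7, 144929931 to 144939925) and Mir5099 rose in both, against 0.0078 genes for independent lists (one-sided Fisher's exact test across genes, p = 2.48e-05, Benjamini-Hochberg adjusted over 24 overlaps 8.05e-05). That test rests on these 2 genes, of which Mir5099 is uncertain as a small RNA gene, and both were called in the opposite direction to Ezh2-KO between the wild-type lines. Grb10 (chromosome 11, 11930508 to 12038683), an imprinted growth inhibitor gene, fell in both, against 0.031 expected (exact p = 0.030, adjusted 0.066). With no call required, 23 genes had an absolute log2 fold change of at least 1 in the same direction in both, 7 higher and 16 lower, and 0 in opposite directions, against 0.63 expected in the same direction. Of the 32 Ezh2-KO calls, 28 had the same sign in Suz12-KO, and of the 37 Suz12-KO calls, 33 had the same sign in Ezh2-KO, beside 58.9% of all genes. Lefty2, Hist1h1t, Vim and B3gnt3, called in Suz12-KO, stood at 1.20, 1.14, 1.09 and 1.06 in Ezh2-KO without a call. Gsto1, called in Ezh2-KO, stood at 1.08 in Suz12-KO. Among decreases, Frem2 stood at -1.39 and -1.34 and Anxa5 at -1.13 and -1.39 in Ezh2-KO and Suz12-KO, called in neither. Adgre5 was called in Ezh2-KO at -1.45 and stood at -1.13 in Suz12-KO.

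The comparison of Ring1A+B-DKO with E14-WT asks what PRC1 loss does to transcripts. Per the authors' deposited table, 469 genes rose and 122 fell. Gene models (symbols with Gm or Rik) set aside, the largest increase was Rprl3, at a log2 fold change of 9.83, followed by Dppa3 (ENSMUSG00000046323, chromosome 6, 122626410 to 122630272) at 4.19 and Rprl2 at 3.90. Tdrd1 and Tex101, both germ cell genes, rose by 3.62 and 3.50. Ftl1-ps1, Trank1, the CDK inhibitor gene Cdkn1c, Rhox6 and the keratin gene Krt18 rose by 3.35, 3.24, 3.21, 3.13 and 3.10. Vim (chromosome 2, 13573927 to 13582826) fell most, to -3.57, in contrast to its increase in Suz12-KO. The difference between these 2 comparisons was not tested. Mylpf, Serpina3m, the titin gene Ttn and Pnma2 fell to -2.87, -2.53, -2.44 and -2.40. Hmga1, the oligodendrocyte lineage factor Olig2, Myo1f, Haus4 and Apoa2 followed at -2.39, -2.37, -2.33, -2.31 and -2.26. Several of these genes have near-identical copies, and their values are uncertain. Hmga1 stood beside Hmga1b at 1.48, and Ftl1-ps1 beside Ftl1 at -0.86, neither partner called. Eno1 fell to -2.11 while its copy Eno1b rose by 2.95. Rprl3 and Rprl2 are named for their likeness to the ribonuclease P RNA gene Rpph1, which stood at -0.67, and as small RNA genes they are uncertain too.

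Germline genes rose together in Ring1A+B-DKO. The authors' deposited table had increases in 14 of 25 germline and meiosis genes and decreases in 0, against 0.60 increases expected (one-sided Fisher's exact test across genes, Benjamini-Hochberg adjusted p = 1.01e-14 over 184 tests of lists). Their median log2 fold change was 1.74. Besides Tdrd1 and Tex101 they included Mael at 2.93, Mov10l1 at 2.85, Sycp1 at 2.65 and Piwil2 at 2.43, genes of the piRNA pathway or the synaptonemal complex. Uncalled members included Stra8 at 1.44 and Dazl at 1.13.

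**Figure D2:**
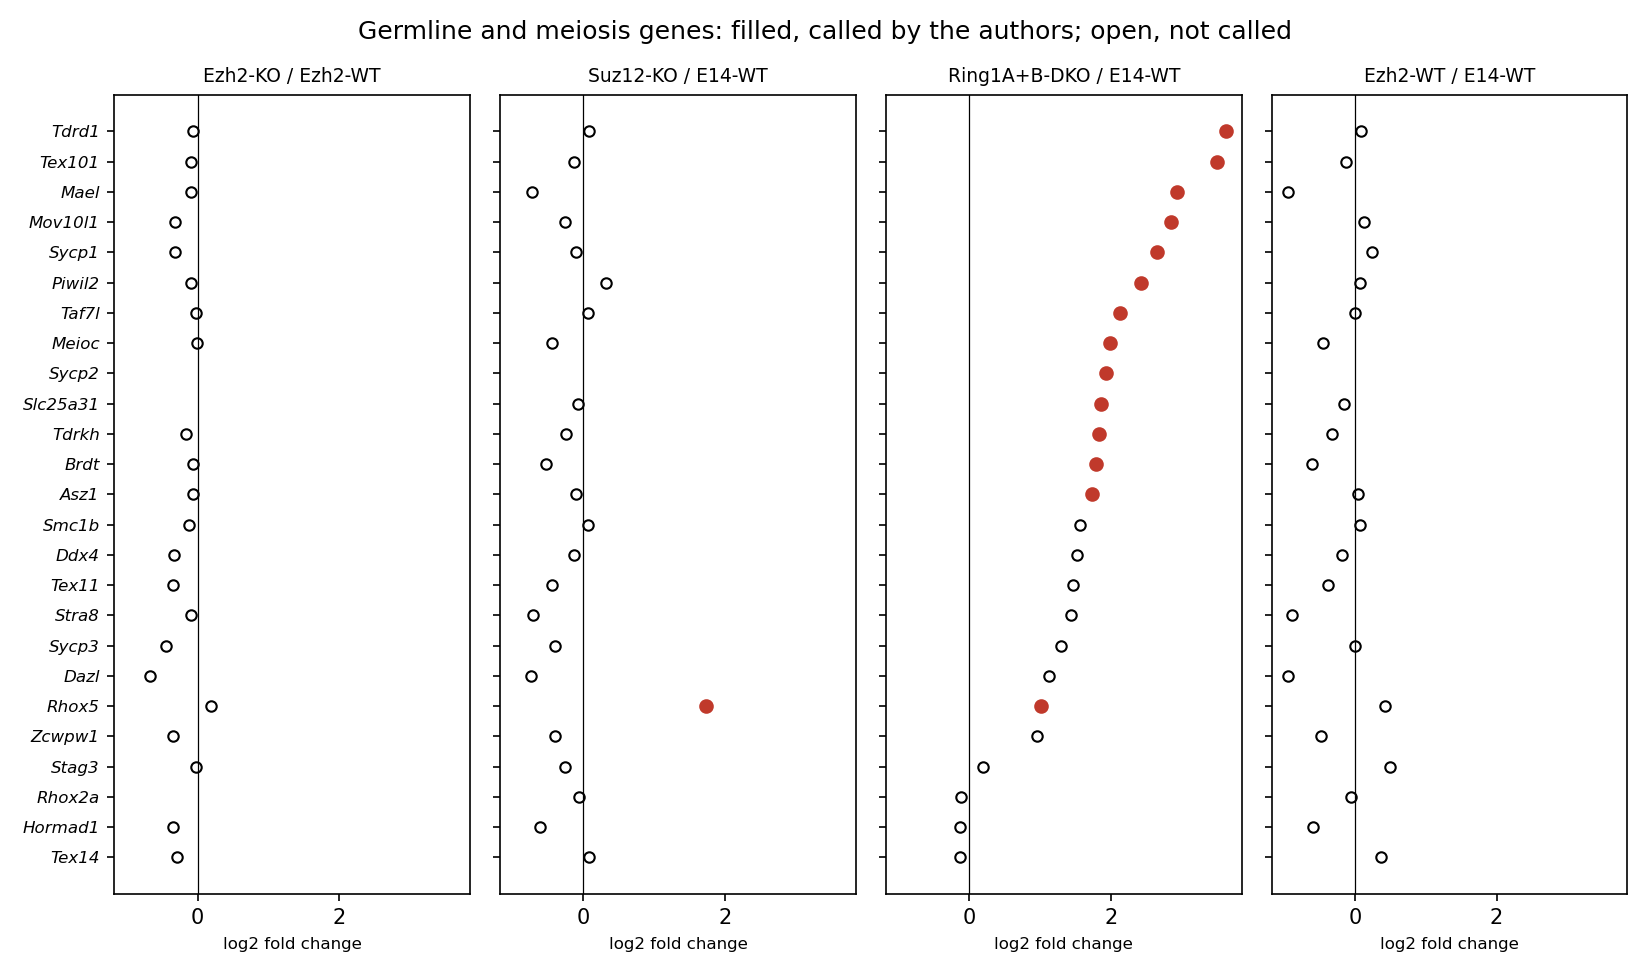
Log2 fold change (horizontal axis) of each germline and meiosis gene in the 4 comparisons, as deposited by the authors. Filled points are genes the authors called and open points genes they did not. In Ring1A+B-DKO 14 of 25 genes were called, all higher, against 0 in Ezh2-KO, 1 in Suz12-KO and 0 between the wild-type lines.

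The medians of the Hox, developmental transcription factor, endoderm, trophoblast and mesoderm lists lay above the random range in Ring1A+B-DKO in the authors' deposited table, and that of the neural list within it. A gene without reads in E14-WT can only have a value above 0 here, which applied to 19 of 34 Hox genes, 34 of 88 developmental transcription factors, 5 of 22 endoderm genes and 7 of 18 mesoderm genes. With genes that had reads in E14-WT alone, against random lists of such genes, those medians were 0.65, 0.66, 0.70 and 0.62 and stayed above the range. Hox genes had a median of 0.66 over all 34, and 4 rose (exact adjusted p = 0.11, not past 0.05). These were Hoxd13 at 2.51, Hoxa9 at 2.14, Hoxd8 at 1.94 and Hoxd9 at 1.56. Of 88 developmental transcription factors 10 rose, Barx1 at 2.75 and Tbx2 at 2.62 among them, and 2 fell, Olig2 and Olig1 (-1.79). Increases were more than the 2.10 expected (exact adjusted p = 0.0021). Of 22 endoderm genes 5 rose, which were Col4a2 at 2.83, Gata6 at 2.69, Gata4 at 2.39, Col4a1 at 2.00 and Dab2 at 1.87 (exact adjusted p = 0.0043). Of 14 trophoblast genes 5 rose, Krt18 and Krt8 (2.62) among them, with a list median of 1.17 (exact adjusted p = 7.71e-04). Of 18 mesoderm and primitive streak genes 2 rose, Tbx20 at 2.77 and Mesp2 at 1.77 (exact adjusted p = 0.38, not past 0.05). Feeder fibroblast markers, included to watch for another cell type, also stood above the random range. Their median was 0.51 over 12 genes, and 0.74 over the 8 with reads in E14-WT, both above the random range, and 2 of the 12, Thy1 and Col5a1, rose, by 1.66 and 1.33 (exact adjusted p = 0.23). Of the 12, 10 stood above 0, Fn1 stood at -0.56 without a call, and 7 had values shared with other genes. Neural genes gave 0 increases and 3 decreases among 18, namely Olig2, Tubb3 (-2.10) and Stmn2 (-1.86), against 0.11 decreases expected (exact adjusted p = 0.0046). Their median was 0.21 and their mean -0.0071.

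Imprinted genes moved both ways in Ring1A+B-DKO, with 7 increases and 3 decreases among 29 in the authors' deposited table (exact adjusted p = 3.79e-04 and 0.015). Their median of 0.48 lay above the random range. Cdkn1c, H19 at 2.79, Sfmbt2 at 2.52 and Igf2 at 2.35 rose, while Mirg, Peg3 and Rian fell to -1.64, -1.33 and -1.17. Grb10 rose by 1.52 here and fell in both PRC2 knockouts. Of 12 general pluripotency genes 2 fell, Lin28a at -1.74 and Sall4 at -1.46 (exact adjusted p = 0.044). The list median of -0.31 was below the random range but inside it against random lists matched on shared values (percentile 1.71), and against random lists of genes with reads in E14-WT (0.72). Naive pluripotency genes gave 3 increases, Dppa3, Fbxo15 (1.32) and Klf4 (1.04), and 1 decrease, Nr0b1 (-1.51), among 17. Their median was -0.21 and their mean 0.21. Replication-dependent histones stood at a median of -0.53 over 21 genes, 0 of them called. Among PRC1 subunits Ring1, Phc1 (-1.68) and Kdm2b (-1.32) fell and Phc2 (1.15) rose. The decreases gave an exact adjusted p of 0.0075, but Ring1 was deleted by design, and without Ring1 and Rnf2 it was 0.11, not past 0.05. The 12 PRC2 subunits had 0 calls. Of 18 p53 targets 3 rose, Perp at 1.51, Ddit4l at 1.36 and Plk2 at 1.12 (exact adjusted p = 0.11). Formative and primed epiblast genes had Otx2 higher at 1.88 and Lefty1 lower at -1.77, and MEK-ERK targets had Fos higher at 1.97 and Etv5 lower at -2.06. Rplp1 and Rpl3 fell among ribosomal proteins, to -1.21 and -1.01, and Uhrf1 to -1.01 among DNA methylation genes. Both ribosomal genes have near-identical copies, as do Uhrf1, Lefty1, Etv5, Kdm2b, Rian and Dppa3, so their values are uncertain. The 2-cell-like and WNT target lists had 0 calls. The medians of the p53, formative, MEK-ERK, ribosomal, DNA methylation, 2-cell-like and WNT lists lay within the random range. At an absolute log2 fold change of at least 2, 166 called genes remained, and 1595 genes passed 1 when no call was required.

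**Figure D3:**
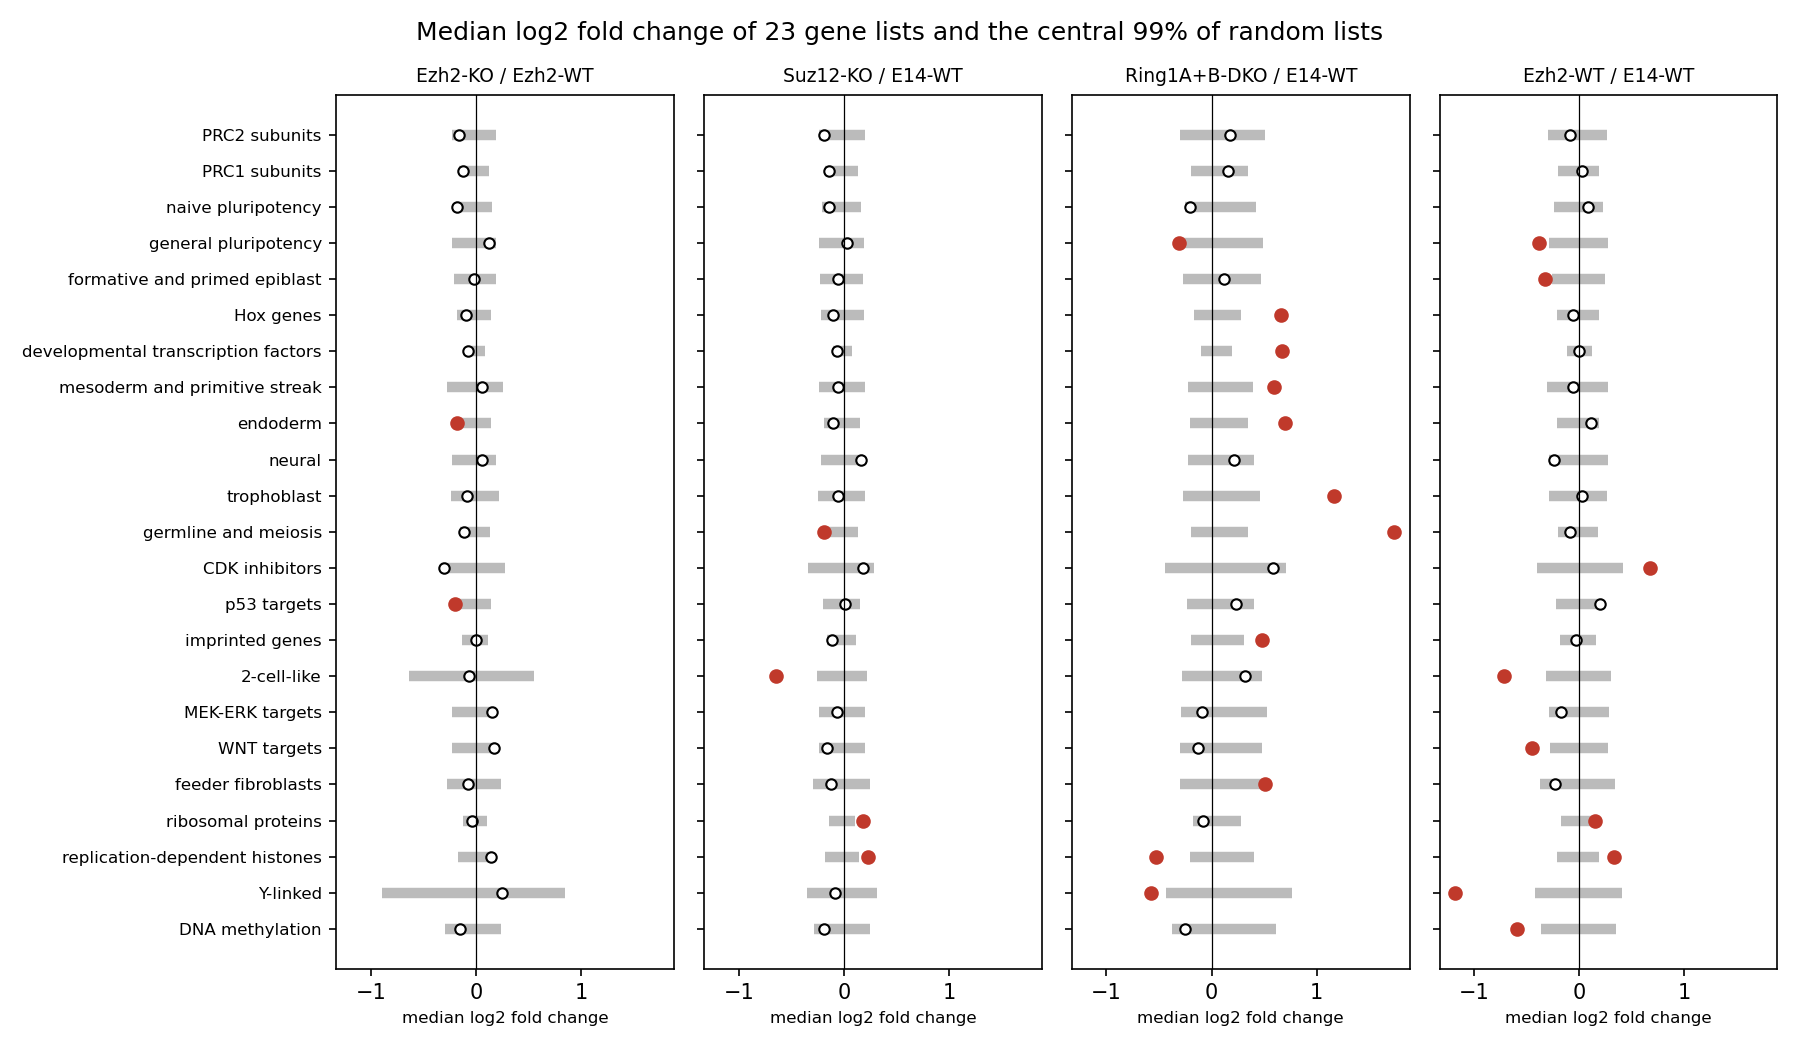
Median log2 fold change (horizontal axis) of 23 gene lists in each comparison, with the central 99% of 10000 random lists of the same size in grey. Red points lie outside that range, 8 above and 3 below it in Ring1A+B-DKO, against 2 in Ezh2-KO, 4 in Suz12-KO and 9 between the wild-type lines.

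The comparison of the wild-type lines gives a difference without any knockout, beside which the knockouts are read. It can come from the background or from the state of the cultures, which were not told apart. The authors' deposited table had 67 genes higher in Ezh2-WT than in E14-WT and 46 lower. Beside the gene model Gm13841 at 2.88, Gata2 and Gpnmb were higher by 2.58 each, the neuronal enolase gene Eno2 by 2.23, Ripply3 by 2.19 and the aquaporin gene Aqp8 by 2.18. Lrrk1, Cyba, Bhlhe41, Nkx6-2 and Sdc3 were higher by 2.14, 2.13, 2.08, 2.07 and 2.01. Nod1, an innate immune receptor gene, was lower at -3.15, and the Y-linked genes Ddx3y and Uba1y at -2.67 and -2.36. Hspa8, Myo1f, A2m, S100a6, Reep1, Obox6 and Vim followed at -2.35, -2.25, -2.12, -2.01, -2.01, -1.96 and -1.92. Hspa8, Obox6 and Uba1y have near-identical copies. The pluripotency factor Nanog, which has a near-identical copy as well, was lower at -1.15, and the methyltransferase cofactor Dnmt3l at -1.56. The Y-linked list stood at -1.18 over 6 genes, with 2 called lower. WNT targets (-0.45), DNA methylation (-0.59), 2-cell-like (-0.72), general pluripotency (-0.38) and formative and primed epiblast genes (-0.32) also lay below the random range, with 1, 1, 0, 0 and 1 decreases. CDK inhibitors (0.67), histones (0.33) and ribosomal proteins (0.15) lay above it with 0 calls. The ribosomal proteins came inside the range with the mean (percentile 52.6).

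Part of the Ezh2-KO calls mirrored this difference between the wild-type lines. Among the 32 Ezh2-KO calls of the authors' deposited table, 12 were also called between the wild-type lines, all in the opposite direction. Gata2, Sdc3, Eno2, Bhlhe41, Ripply3, Acadl, Rrm2b and E330020D12Rik were higher in Ezh2-WT than in E14-WT and fell in Ezh2-KO. S100a6, Ccnd1, Mir5099 and Sgk1 did the reverse. Both comparisons use the Ezh2-WT libraries. Their correlation was r = -0.50 over 17175 genes, and a simulation without any effect gave -0.50 for a shared group. The covariance was -0.059, larger in size than the -0.042 if all variance of the less variable comparison were chance. The simulation had equal spread, whereas the SDs were 0.29 in Ezh2-KO and 0.39 in Ezh2-WT. The like values of r therefore do not show that the shared group alone gives the mirror.

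The comparisons against E14-WT share its libraries, which alone correlates their fold changes. For Suz12-KO and Ring1A+B-DKO the authors' deposited table gave r = 0.065 over 17757 genes, beside 0.51 in the simulation without effects. That simulation had equal spread, whereas these SDs were 0.30 and 0.57, so r alone does not place the pair below it. Their covariance was 0.011 beside 0.045. Dppa3, Gpc3, Rhox5 and Sfmbt2 rose in both, against 0.38 genes for independent lists (exact adjusted p = 0.0012), and Dusp27 and Ttn fell in both, against 0.14 (exact adjusted p = 0.022). These overlaps are not independent of the shared controls. In Ezh2-WT, with no knockout, Dusp27 was called lower as well, at -1.64. Ttn stood there at -0.81, Dppa3 at 1.25, Rhox5 at 0.42 and Sfmbt2 at 0.09, none of them called. Ring1A+B-DKO and Ezh2-WT shared 15 increases and 9 decreases against E14-WT, beside 1.65 and 0.31 for independent lists (exact adjusted p = 3.75e-10 and 1.70e-10). Their r was 0.35 beside 0.50 in the simulation. Their covariance was 0.081, beside 0.076 if all variance of the less variable comparison were chance. The simulation had equal spread, whereas the SDs were 0.57 and 0.39, so r alone does not place this pair below the level of shared controls. Aqp8, Bhlhe41, Eno2, Gata2 and Gpnmb were among the shared increases, and Vim, Nod1, Myo1f and Lefty1 among the shared decreases. Suz12-KO and Ezh2-WT shared 6 decreases, against 0.055 for independent lists (exact adjusted p = 1.43e-10), Acan, Dusp27 and Reep1 among them. Their r was 0.23 beside 0.50 and their covariance 0.027 beside 0.045. With SDs of 0.30 and 0.39 the same limit applies to this r. Between Ezh2-KO and Ring1A+B-DKO, which share no library, r was -0.14 over 16786 genes. Of the genes that fell in Ezh2-KO, 6 rose in Ring1A+B-DKO, against 0.62 expected (exact adjusted p = 8.05e-05). These were Adcy1, App, Bhlhe41, Eno2, Gata2 and Grb10. Bhlhe41, Eno2 and Gata2 were also called higher in Ezh2-WT than in E14-WT, at 2.08, 2.23 and 2.58. Their fall in Ezh2-KO may thus reflect the Ezh2-WT control, which the p does not take into account.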

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

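Counts by size alone, the sign in the headers, genes with a value of their own, matched random lists and lists of genes with reads in the control, and PRC1 subunits without the deleted genes, were chosen after seeing the data. No paired analysis was possible because the table holds no values per sample. For the same reason leaving out replicates, other wild-type controls, other count models and filters were not run, nor were other adjusted p thresholds or the upper part of the mean level, and depth limits cannot be stated. A 1.5-fold threshold removed no called gene, since each exceeds it, and centring on the median left 32, 37, 586 and 113 calls. Counts are given in the order Ezh2-KO, Suz12-KO, Ring1A+B-DKO and wild-type lines. An absolute log2 fold change of at least 2 left 3, 3, 166 and 21 calls, and 0 genes called in both PRC2 knockouts. By size alone, at least 1 gave 122, 152, 1595 and 431 genes, with 23 shared by the PRC2 knockouts, and at least 1.5-fold gave 981, 1078, 4370 and 2242. Fewer or more genes pass by the construction of these thresholds. With the sign in the headers, the called genes higher in the named group would be 21 in Suz12-KO, 122 in Ring1A+B-DKO and 46 in Ezh2-WT. Then 0 calls would be shared by the PRC2 knockouts in one direction and r would be -0.344. The correlation of 0.34 became 0.29 as rho, 0.37 over genes with a value of their own and 0.227 without the 5% largest changes, where the cause was not tested. Of 26 list medians outside the random range, 22 stayed outside under each alternative run. With the mean, the germline and meiosis list in Suz12-KO (-0.169) and the ribosomal proteins in Ezh2-WT (0.000636) came inside. With matched random lists, general pluripotency in Ring1A+B-DKO (-0.314), p53 targets in Ezh2-KO (-0.200) and ribosomal proteins in Ezh2-WT (0.147) came inside. With genes that had reads in the control, in lists and random lists alike, 25 of the 26 stayed outside, and general pluripotency in Ring1A+B-DKO (-0.314, percentile 0.72) came inside. The cause was not tested. Of the 66 other list medians, 10 moved outside with the mean, 1 with matched lists and 2 with genes that had reads in the control. Neural genes in Suz12-KO (0.177, 0.165 and 0.245) did so with each of these. Histones in Ezh2-KO (0.138, percentile 99.51) were the other change with genes that had reads in the control. The other changes with the mean were endoderm and feeder fibroblasts in Suz12-KO, germline, WNT and histones in Ezh2-KO, CDK inhibitors and ribosomal proteins in Ring1A+B-DKO, and endoderm and neural in Ezh2-WT. Without the deleted genes, decreases among PRC1 subunits in Ring1A+B-DKO no longer passed (adjusted p = 0.109), as 1 of the 3 was Ring1. Mean and median differed in sign in 12 of 92, 0 of them outside the range.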

Other observations

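The tests of this part were chosen after the results were seen, except that on antigen presentation genes away from chromosome 17, whose values had not been looked at.

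Reads appeared in Ring1A+B-DKO at many genes that had none in E14-WT. The authors' deposited table left 20921 genes with no reads in E14-WT, and 2259 of them had reads in Ring1A+B-DKO, 1064 in Suz12-KO and 1170 in Ezh2-WT. Among 7267 protein-coding genes the numbers were 1388, 366 and 526, and among 12198 genes annotated with another class 797, 647 and 602, genes without an annotation match left out. The ratio of Ring1A+B-DKO to Suz12-KO was 3.79 for protein-coding genes and 1.23 for the other classes. Of 23 Hox genes without reads in E14-WT, 19 had reads in Ring1A+B-DKO, 0 in Suz12-KO and 6 in Ezh2-WT. Of 41 developmental transcription factors the numbers were 34, 4 and 7. The depth of the groups is unknown, and 51 of the genes silent in E14-WT were called in Ring1A+B-DKO, Gata6, Hoxa9, Msx1 and Tbx2 among them.

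Several Y-linked genes had no reads in either Ezh2 line. Ddx3y, Eif2s3y, Kdm5d, Zfy1 and Usp9y have no value in the Ezh2-KO comparison of the authors' deposited table, so neither Ezh2-KO nor Ezh2-WT had reads there. Those genes have values between the wild-type lines, so E14-WT had reads there. Uty, Uba1y, n-R5s1 and Gm47283 have values in the Ezh2-KO comparison, of 0.24, -0.07, -0.07 and 0.12. The values of Uty and Uba1y are shared with other genes, Uba1y's with Tdrd1, as can occur for genes with few reads. Between the wild-type lines Gm47283 stood at 1.11 and n-R5s1 at 0.32, and Uty at -1.15, none called. In Ring1A+B-DKO the Y-linked list stood at -0.57 over 6 genes, none called. Between the wild-type lines, chromosome medians over genes with values of their own ran from -0.13 (chromosome 18) to 0.12 (chromosome 6). Chromosome 6 was lowest in Ezh2-KO, at -0.07, a comparison that shares the Ezh2-WT libraries. An extra copy in every cell beside a diploid control would give 0.58, if values were not drawn towards 0. The medians therefore do not exclude an extra copy in part of the cells.

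Calls in Ring1A+B-DKO were dense around Ring1 itself. Of 252 genes of the authors' deposited table within 5 Mb of it, 19 were called (7.54%) against 2.97% elsewhere (two-sided Fisher's exact test, p = 2.63e-04, adjusted over 16 tests 0.0042), more than in any of the 63 other windows of 10 Mb with at least 100 genes (highest 6.87%), as was the share without Ring1 itself (18 of 251, 7.17%). Of the 19, 10 were antigen presentation genes, 7 higher, such as Tap1 and Psmb9, and 3 lower (Gm10499, Gm8909, H2-M5), of which H2-Q7, H2-Q2 and Gm8909 have near-identical copies, and without these and Ring1 the share was 3.72%, reached or passed by 12 windows. Line-specific DNA linked to the targeted allele may contribute, and this remainder neither excludes nor requires it, because it leaves out called genes. A pathway response is a candidate explanation for the 7 higher antigen presentation genes but not the 3 lower ones, since 17 such genes elsewhere had a median of 0.47 (percentile 99.8 of random lists; 0.42 and 99.6 for the 16 with reads in E14-WT), 1 of them called (Ifngr1).

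Near-identical copies in Ring1A+B-DKO sometimes moved apart, such as Rpl3 at -1.01 and Rpl3-ps1 at 1.59, both called in the authors' deposited table. If reads had moved between copies, for example through sequence differences of the line, the copy should go the opposite way in most cases. It did so in 24 of 49 called genes with a measured copy (49.0%, exact 95% interval 34.4 to 63.7), and in 7 of 14 called genes that are not protein coding (50%, 23.04 to 76.96). A wider definition, any aligned stretch of 100 nt, gave 42 of 88. The intervals hold 50%. They treat genes as independent, but in 6 of the 24 the copy was itself called the opposite way. Such pairs, Eno1 and Eno1b among them, entered once from each side. The measured copies include short matches to small RNA genes, such as Gm22993 for Ctcfl and Slc28a3, and some copy values are shared by several genes. With 469 of 591 calls higher, 50% is not an established base rate either. The share therefore cannot speak for or against moved reads. They stay possible for single pairs, and no biological explanation was tested.

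The 12 genes the authors called in opposite directions in Ezh2-KO and between the wild-type lines may reflect values particular to the Ezh2-WT libraries, by chance or by the state of those cells. Suz12-KO against E14-WT uses no Ezh2-WT library, but it shares E14-WT with the comparison of the wild-type lines, which can affect the share of same signs. That share was 58.9% over all genes and 49.5% over the 11061 with opposite signs in Ezh2-KO and Ezh2-WT. The cause of the lower share was not tested. Of the 12, 9 had the same sign as in Ezh2-KO (75%, exact 95% interval 42.8 to 94.5), and the interval holds both shares, so the explanation stays open for them, as does PRC2 loss. Of the other 20 Ezh2-KO calls, 19 had the same sign in Suz12-KO (95%, 75.1 to 99.9), which argues against it as the whole explanation for these. It may still hold in part, as 16 of the 20 had the opposite sign in Ezh2-WT (68.3% of genes with values in all 3 comparisons did), and a condition common to the knockout cultures was not tested beside PRC2 loss.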
